A study of Mus musculus with 18 samples.

How the data were processed

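CD4+ T cells of wild-type and ERRα knockout mice were measured on 18 Affymetrix Mouse Genome 430A 2.0 arrays, 3 independent biological replicates in each of 6 groups. Per the labels, the cells were purified by negative magnetic selection, and RNA was amplified and labelled with biotin. The deposited values are log2 signals per probe set, which the authors made with GCRMA, a method that corrects for background and sequence composition. All 18 arrays hold the same sorted values, from 1.83 to 15.4 with a median of 3.55, so they had been quantile normalized after summary.

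Groups were taken from the labels. Of 22690 probe sets, 64 controls, 1555 without a gene and 691 with several genes were left out. Each of the 12393 genes was represented by the probe set with the highest mean over the 18 arrays. A gene was tested where that probe set reached log2 4 on at least 3 arrays, which left 6873 genes. The 10 comparisons were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, equal array weights, a constant prior variance, 12 residual and 2.22 prior degrees of freedom, two-sided tests and no block. P-values were adjusted by Benjamini and Hochberg within each comparison, and an adjusted p under 0.05 counts as passing. The p-values measure the spread between samples. Fold changes are powers of the log2 difference. Where all 3 arrays of the lower group lay under log2 4, the fold was computed against that floor and is given as "at least"; where only their mean did, the arrays under log2 4 were set to it first. Log2 differences, tests and the ranking of genes use the values as given.

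The 50 gene lists were written before the data were examined, as were the comparisons, the tests and the rule for named genes; 46 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Genes were named by this rule: Esrra; the 8 largest rises and 8 largest falls that passed, with no overlap between the groups' arrays (5 and 5 for the inhibitors against resting cells, and no overlap rule for the interaction); up to 4 members of smallest adjusted p of each list described; and Il2, Ifng, Il2ra, Slc2a1, Cpt1a, Cycs and Acadm. Cd69 and Pdk4, also in the rule, were not analysed here. Spike-in control probe sets were read but not tested.

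The activation score is the mean of the genes that rose at least 4-fold with stimulation in knockout arrays minus the mean of those that fell as much. It was compared between groups by a two-sided exact permutation test. Correlations of log2 changes across genes were set beside 100 simulated data sets with no group effect and the same shared arrays, and their errors are jackknife errors over arrays.

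The alternatives were no filter, a floor of log2 6, arrays shifted to a common median, the mean of all probe sets of a gene, the array number as a block, a fit on the compared groups alone, a trended and robust prior, array weights, a limit of 2-fold, and leaving out each array in turn. Added after seeing the data were the arrays numbered 2 and 3 alone, marker means as covariates, and stimulated knockout cells as the reference for the inhibitors. Whether the array numbers pair the samples was checked by correlating the deviations of equally numbered arrays from their group means. All 3 correlations exceeded 0.1 for knockout stimulated against resting, for knockout against wild-type cells at rest (0.645, 0.406 and 0.254) and after stimulation, and for both inhibitors against stimulated wild-type cells. The labels name no shared day or animal.

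The fit was tested on simulated data of the same size with 50 genes at each fold change. It recovered 76% of genes at 1.5-fold, 92% at 2-fold and 100% at 4-fold and 8-fold. It gave 8 false calls, 4.17% of all calls, and 0 in a comparison with no change. The real arrays had residual SDs from 0.123 to 0.404, so these rates may not hold for them. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.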

Results

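RNA from CD4+ T cells of mice aged 6 to 8 weeks was measured on 18 arrays. The cells came from wild-type mice or from mice lacking ERRα, an orphan nuclear receptor encoded by Esrra that activates genes of mitochondrial energy metabolism. The arrays form 6 groups of 3: wild-type resting, wild-type stimulated, knockout resting, knockout stimulated, wild-type with XCT790 and wild-type with compound A. Resting cells were taken directly from the mouse, and stimulation was 12 h with 10 µg of antibodies against CD3 and CD28. XCT790 is an inverse agonist of ERRα, and compound A is named only by its code, as another ERRα inhibitor; both were used at 20 µM. The stimulation field in the labels of the 6 inhibitor arrays says that these cells were not stimulated, whereas the protocol and the series design place both inhibitors in the 12 h stimulation, so each inhibitor was compared with stimulated and with resting wild-type cells. The values are log2 GCRMA signals. Every array held the same set of values, with 11025 probe sets, 48.6% of the total, at or above log2 4, so all changes are relative to the other genes on the array. The number of arrays, 3 per group, limits the precision.

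Bacterial dap RNA, a control added before labelling, separated the 6 untreated wild-type arrays from the other 12. Its 5' probe set read 5.11 ± 0.861 (SD, n = 6 arrays) on the untreated wild-type arrays and 8.00 ± 0.307 (SD, n = 12 arrays) on all others, a difference of 2.89, with no overlap between 3.99 to 6.38 and 7.45 to 8.51. Its 3' probe set read 11.2 and 11.1 on the same arrays. Comparisons of knockout or inhibitor arrays with untreated wild-type arrays therefore cross this split, and group and split cannot be told apart in them. The response to stimulation within each genotype and XCT790 against compound A lie on one side of it.

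**Figure D1:**
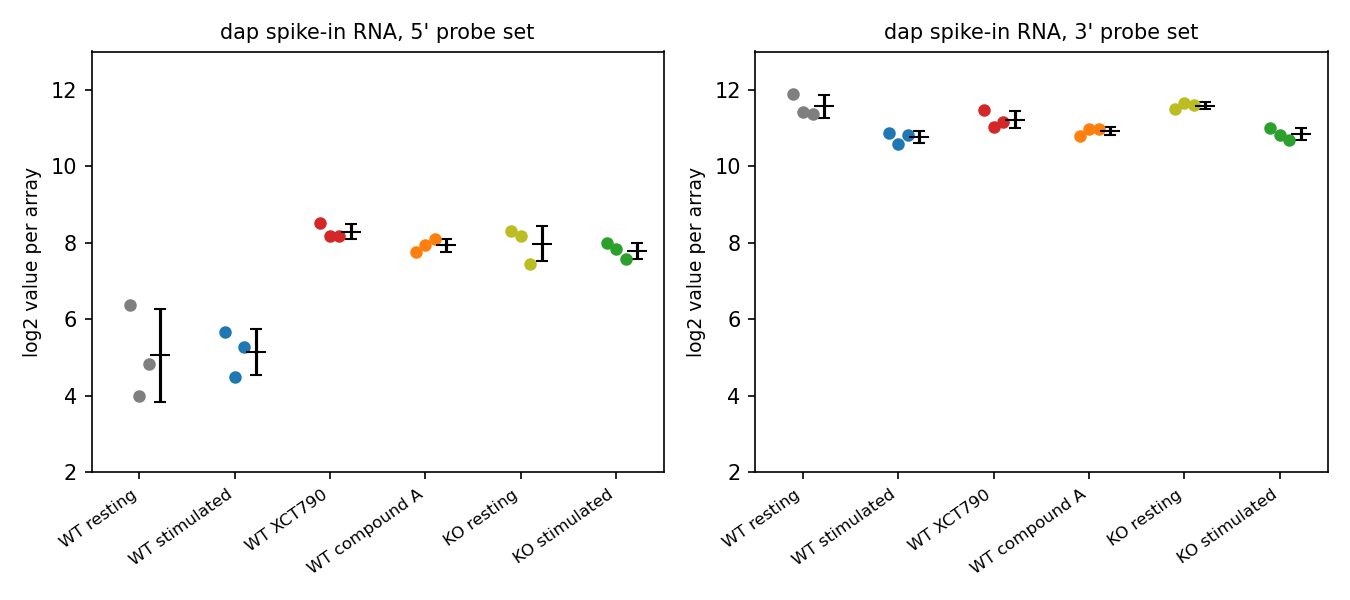
Log2 value per array (y axis) of the 5' and 3' probe sets of the dap control RNA in the 6 groups; points are arrays, bars the mean and SD (n = 3). The 5' probe set lies at 3.99 to 6.38 on the 6 untreated wild-type arrays and at 7.45 to 8.51 on the other 12.

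Esrra was represented by 1 probe set. It read 5.42 ± 0.15 (SD, n = 3) in resting and 5.37 ± 0.09 in stimulated wild-type cells, and 4.55 ± 0.18 in resting and 4.45 ± 0.23 in stimulated knockout cells. The knockout signal was 1.83-fold lower at rest (log2 difference -0.87 ± 0.11, SE; limma adjusted p = 2.16e-04) and 1.89-fold lower after stimulation (-0.92 ± 0.11; adjusted p = 3.31e-04). The labels do not say whether the probe set lies in the deleted part of the gene. The response to stimulation did not pass in either genotype (adjusted p = 0.696 and 0.444). With XCT790 the log2 difference from stimulated wild-type cells was -0.27 ± 0.11 (adjusted p = 0.0450), and with compound A -0.26 ± 0.11 (adjusted p = 0.0902). The XCT790 call ended without wild-type stimulated array 2 or 3 (adjusted p = 0.147 and 0.0804) or XCT790 array 1, 2 or 3 (0.101, 0.0873 and 0.0649), with no filter (0.0740), with arrays shifted to a common median (0.0953), with a trended and robust prior (0.123) and on the arrays numbered 2 and 3 (0.0649). Compound A passed in a fit on the compared groups alone (0.0153) and with array weights (0.02002), and the resting knockout difference was -0.86 with the erythroid covariate and did not pass (0.0587) on a larger error.

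The comparison of stimulated with resting wild-type cells joins activation with 12 h in culture, since resting cells were taken directly from the mouse. Stimulated cells gained cytokine and chemokine transcripts and transcripts of the machinery for ribosomes, protein turnover and biosynthesis, and lost transcripts of resting T cells, macrophages and B cells. Il2, the T cell growth factor, was 111-fold higher, at 11.25 ± 0.11 (SD, n = 3) against 4.46 ± 0.44. Il2ra, a chain of its receptor, was 13.8-fold higher, and Ifng, encoding interferon gamma, 14.2-fold. The largest fitted rises were those of the chemokine Ccl22 (at least 199.9-fold), Lad1 (at least 158-fold), thyroglobulin Tg (at least 64.2-fold), the retinoic acid carrier Crabp2 (at least 63.4-fold), the chemokine Ccl4 (at least 85.2-fold), the branched-chain aminotransferase Bcat1 (at least 39.3-fold) and the cell cycle inhibitor Cdkn1a (at least 39.2-fold). Of 6873 genes tested, 5180 changed, 2542 upward and 2638 downward, 2336 of them at least 2-fold. Genes named for the size of a change, in this and the later comparisons of groups, had all 3 arrays of one group above all 3 of the other, which chance gives for 10% of genes.

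Cytokines and chemokines rose in 17 of 21 genes tested and fell in 2 (camera adjusted p = 0.00139, and 0.427 with an estimated correlation). They include the attractant Ccl1 (at least 11.4-fold) and Lif (at least 16.4-fold). T cell activation markers rose in 14 of 15 (adjusted p = 3.26e-04, and 0.222 with an estimated correlation), among them the transcription factors Irf4 (54.1-fold) and Myc (4.77-fold) and the costimulatory receptors Tnfrsf9 (12.4-fold) and Tnfrsf4 (9.65-fold). All 33 ribosome biogenesis genes rose (adjusted p = 6.48e-14, and 0.218 with an estimated correlation), with Nop16 5.99-fold and Nolc1 5.51-fold higher. Mitochondrial ribosomal proteins rose in 51 of 55 and fell in 2 (adjusted p = 1.70e-11, and 0.309 with an estimated correlation); Mrpl17 was 3.10-fold and Mrps18b 3.69-fold higher. Proteasome subunits rose in 31 of 32 (adjusted p = 1.70e-11, and 0.309 with an estimated correlation), with Psme3 6.97-fold higher. All 10 serine and one-carbon genes rose (adjusted p = 0.00105, and 0.362 with an estimated correlation), including the hydroxymethyltransferases Shmt1 (63.6-fold) and Shmt2 (5.19-fold). Complex I of the respiratory chain rose in 23 of 33 and fell in 7 (adjusted p = 0.00613, and 0.543 with an estimated correlation), with Ndufab1 2.41-fold higher. Glycolysis genes rose in 12 of 16 and fell in 2 (adjusted p = 0.00723, and 0.427 with an estimated correlation). Hexokinase Hk2 was 46.2-fold higher and the phosphoglycerate mutase Pgam1 4.28-fold, whereas the glucose transporter Slc2a3 was 5.09-fold lower and Slc2a1 1.60-fold higher. The counts adjusted over the list alone were the same for these 8 lists.

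Genes of quiescent and naive T cells fell in 14 of 18 and rose in 2 (adjusted p = 0.00114, and 0.427 with an estimated correlation), including the glucose-uptake inhibitor Txnip (11.6-fold), the interleukin-7 receptor Il7r (23.4-fold) and the transcription factor Klf4 (14.7-fold). Liver X receptor targets fell in 6 of 9 and rose in 1 (adjusted p = 0.0162, and 0.222 with an estimated correlation); the cholesterol transporters Abca1 and Abcg1 were at least 53.4-fold and 8.22-fold lower. Cholesterol synthesis genes rose in 15 of 19 and fell in 2 (adjusted p = 0.00174, and 0.514 with an estimated correlation), with Idi1 8.48-fold and Sqle 4.63-fold higher. Fatty acid oxidation genes rose in 3 and fell in 7 of 19 and did not pass as a list (adjusted p = 0.503, direction down, with a median of 0.04 and a mean of -0.40). Cpt1a, which carries fatty acids into mitochondria, was 14.9-fold lower. Markers of macrophages fell in 13 of 16 (adjusted p = 8.13e-04, and 0.518 with an estimated correlation), among them Csf1r (at least 135-fold) and the complement gene C1qa (at least 41.5-fold). Markers of B cells fell in 11 of 12 (adjusted p = 0.00663, and 0.518 with an estimated correlation), with Cd79a at least 19.2-fold lower. The counts adjusted over the list alone were the same for these 6 lists. Other large fitted falls were the adhesion molecule Vcam1 (at least 77.4-fold), carbonic anhydrase Car1 (at least 109-fold), the iron exporter Slc40a1 (at least 58.2-fold), the Notch regulator Dtx1 (179-fold), the glucocorticoid enzyme Hsd11b1 (173-fold) and Fcna (at least 39.0-fold). Of 46 lists, 22 passed with a preset correlation and 0 with an estimated one.

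The response of knockout cells to the same stimulus asks whether activation proceeds without ERRα. Knockout cells raised Il2 at least 105-fold, Il2ra 26.2-fold, Ifng 17.2-fold, Ccl22 at least 259-fold, Lad1 at least 138-fold, Ccl4 at least 123-fold, Crabp2 at least 39.9-fold and Cdkn1a at least 69.4-fold. Tg rose at least 90.02-fold and Cxcl9, an interferon-induced chemokine, at least 100.7-fold. Of 6873 genes, 5042 changed, 2589 upward and 2453 downward; 2280 rose and 2229 fell in both genotypes and 8 moved in opposite directions. All 33 ribosome biogenesis genes rose (adjusted p = 7.69e-14, and 0.147 with an estimated correlation). Mitochondrial ribosomal proteins rose in 50 of 55 and fell in 2 (adjusted p = 8.67e-10, and 0.387 with an estimated correlation). Cytokines and chemokines rose in 17 of 21 and fell in 1 (adjusted p = 2.06e-04, and 0.387 with an estimated correlation). Complex I genes rose in 19 of 33 and fell in 4 (adjusted p = 0.0208, and 0.661 with an estimated correlation). Cycs, encoding cytochrome c, was 1.66-fold higher, against 1.82-fold in wild-type cells, and Cpt1a 8.17-fold lower. All 5 erythroid markers fell (adjusted p = 0.00865, and 0.431 with an estimated correlation), with Ermap at least 131-fold and the transcription factor Klf1 at least 73.6-fold lower. All 7 neutrophil markers fell (adjusted p = 0.0364, and 0.558 with an estimated correlation), with the myeloperoxidase gene Mpo at least 40.6-fold lower. The counts adjusted over the list alone were the same for these 6 lists. The largest fitted falls also included Csf1r (at least 216-fold), Fcna (at least 111-fold), Slc40a1 (at least 102-fold), Vcam1 (at least 129-fold), Car1 (at least 121-fold) and the water channel Aqp1 (at least 70.2-fold). Over 1.5 times as folds, leaving out 1 array moved these log2 differences. Ermap was -7.97 (from -8.58), Fcna -7.92 (from -8.59) and Mpo -5.64 (from -6.53) without knockout resting array 1. Car1 was -9.88 (from -8.11), Cxcl9 7.56 (from 8.32), Mpo -8.12 and Vcam1 -8.90 (from -8.27) without knockout stimulated array 1. Car1 was -7.23 and Mpo -5.74 without knockout stimulated array 2 or 3. With no filter on dim probe sets the count was 8197 of 12393 genes.

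The interaction of genotype and stimulation tests the difference of the responses. It passed for 62 genes, 33 more upward in knockout cells and 29 more downward. The fitted differences rest partly on values under log2 4, so each is also given with these set to log2 4. Il6 differed by 3.44 ± 0.66 (SE; 2.96 from log2 4; adjusted p = 0.0272), with 7.17 ± 1.10 (SD, n = 3) in stimulated knockout and 3.74 ± 1.02 in stimulated wild-type cells; the call ended without wild-type resting array 2 or 3 (adjusted p = 0.0607 and 0.0707) or wild-type stimulated array 3 (0.0538). Il12rb2, a chain of the interleukin-12 receptor, differed by 2.04 ± 0.33 (0.60 from log2 4; adjusted p = 0.0125) and reached 4.60 ± 0.14 in stimulated knockout cells, while the other 3 groups lay under log2 4. For Rhd and Slc4a1, of the red cell membrane, the difference was -5.47 ± 0.74 (-4.54 from log2 4; adjusted p = 0.00294) and -5.08 ± 0.87 (-4.99; adjusted p = 0.0127). It was -4.68 ± 0.97 (-4.15) for Cldn13, -4.25 ± 0.85 (-3.48) for Aldh1a1, -4.20 ± 0.47 (-2.75) for Tlcd4, -4.17 ± 0.77 (-2.80) for the blood group gene Kel, -3.94 ± 0.68 (-2.28) for the sphingosine kinase Sphk1 and -3.88 ± 0.82 (-3.80) for Rhag. These 8 genes were higher in resting knockout cells and under log2 4 on all stimulated arrays. Their difference is that of the resting cells and measures none after stimulation. The same holds for Klrg1, 2.80 ± 0.57 (2.01), Mcoln3, 2.198 ± 0.40 (1.23), Nacc2, 2.29 ± 0.26 (1.85), and Rab3d, 1.33 ± 0.15 (1.23), which were lower in resting knockout cells. Tbx6, at 1.33 ± 0.19, lay under log2 4 on all 12 arrays, so no size can be given. The enkephalin gene Penk differed by 2.06 ± 0.41 (1.97), with 6.19 and 6.92 in resting and stimulated wild-type and 4.63 and 7.42 in knockout cells. A fit on the 4 groups alone ended the calls of Slc4a1, Sphk1, Aldh1a1, Cldn13, Il6, Kel, Klrg1, Mcoln3, Penk and Rhag (adjusted p = 0.0796 to 0.108), a fit with no filter those of Aldh1a1, Cldn13, Il6, Klrg1, Penk and Rhag (0.0517 to 0.0833), and the arrays numbered 2 and 3 those of Klrg1 (0.110) and Mcoln3 (0.0738). Leaving out 1 array ended the call for Aldh1a1 without wild-type resting array 2 or 3, wild-type stimulated array 1, 2 or 3 or knockout stimulated array 1, 2 or 3 (adjusted p = 0.0539 to 0.0922), and for Cldn13 without wild-type resting array 3, wild-type stimulated array 1, 2 or 3, knockout resting array 1 or knockout stimulated array 1, 2 or 3 (adjusted p = 0.0555 to 0.102). It ended the call for Kel without wild-type resting array 2 or 3, wild-type stimulated array 1, 2 or 3 or knockout stimulated array 2 or 3 (adjusted p = 0.0520 to 0.0647). It also ended the call for Klrg1 without wild-type resting array 1 or 2, wild-type stimulated array 1, 2 or 3, knockout resting array 1 or knockout stimulated array 1, 2 or 3 (adjusted p = 0.0549 to 0.0918), and for Mcoln3 without wild-type resting array 2, wild-type stimulated array 2 or 3 or knockout stimulated array 2 or 3 (adjusted p = 0.0541 to 0.0616). The remaining calls lost were Penk without wild-type resting array 1, 2 or 3, wild-type stimulated array 2 or 3 or knockout stimulated array 2 or 3 (adjusted p = 0.0549 to 0.0936), and Rhag without wild-type resting array 2 or 3, wild-type stimulated array 1, 2 or 3, knockout resting array 1 or knockout stimulated array 1, 2 or 3 (adjusted p = 0.0609 to 0.106). Sizes that moved by over 1.5 times as folds follow. Rhag was -4.89 and -3.23 without wild-type resting arrays 1 and 2. Kel was -3.17 and Sphk1 -3.27 without knockout resting array 1, and Sphk1 -4.78 without array 3. Il6 was 2.81 without knockout stimulated array 1. Aldh1a1, Cldn13, Klrg1, Rhd and Slc4a1 moved as at rest (below). Il2, Ifng and Il2ra did not pass (adjusted p = 0.877, 0.798 and 0.166), though Il2ra did with array weights (0.0196). Cell cycle genes passed as a list, downward, with 0 of 25 members past the test (14 down and 1 up adjusted over the list alone; median -0.96; adjusted p = 2.71e-09; 0.526 with an estimated correlation). Mitochondrial ribosomal proteins also passed downward, with 0 of 55 members past the test (0 adjusted over the list alone; median -0.15; adjusted p = 2.18e-06; 0.526 with an estimated correlation). Cell cycle genes higher at rest in knockout cells (below) can alone turn that list down. Of 46 lists, 17 passed with a preset correlation, 0 with an estimated one and 0 with fry (cell cycle 0.147, mitochondrial ribosome 0.189). The count of genes was 123 with the array number as a block, 1222 with array weights, 38 in a fit on the 4 groups alone, 39 at a floor of log2 6 and 574 on the arrays numbered 2 and 3. It was 22, 27 and 34 without wild-type stimulated arrays 2, 3 and 1, 29 and 27 without wild-type resting arrays 2 and 3, 29 and 26 without knockout stimulated arrays 2 and 3, and 124 and 141 without knockout resting arrays 2 and 3.

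Resting knockout against resting wild-type cells asks what differs before activation, and the largest fitted rises lay in transcripts of red cell precursors and neutrophils. All 5 erythroid markers were higher in knockout arrays (adjusted p = 1.26e-06; 0.727 with an estimated correlation), as were 5 of 7 neutrophil markers (adjusted p = 1.24e-05; 0.727 with an estimated correlation), with the same counts adjusted over the list alone. The erythroid markers averaged 8.69 ± 1.08 (SD, n = 3) against 5.19 ± 1.45, and the neutrophil markers 7.79 ± 1.30 against 4.94 ± 0.672. By fitted difference the largest rises were Rhd (at least 23.3-fold; adjusted p = 1.31e-05), the anion exchanger Slc4a1 (34.1-fold) and the erythroid transcription factor Klf1 (19.9-fold), the neutrophil granule proteases Prtn3 (at least 12.9-fold) and Ctsg (at least 11.6-fold), Cldn13 (25.7-fold), the retinal dehydrogenase Aldh1a1 (at least 11.1-fold) and Tlcd4 (at least 6.75-fold). Cell cycle genes rose in 13 of 25 (19 adjusted over the list alone; adjusted p = 2.04e-10; 0.727 with an estimated correlation), including the cyclins Ccne2 (5.96-fold) and Ccne1 (3.06-fold; adjusted p = 0.0503 without wild-type resting array 3), the replication gene Mcm2 (1.69-fold) and the mitotic kinase Aurkb (3.93-fold), on the same arrays that carried the erythroid markers. NRF2 targets rose in 4 of 11, the same adjusted over the list alone (adjusted p = 6.63e-04; 0.727 with an estimated correlation), with the glutathione synthesis gene Gclm 2.49-fold higher. The largest fitted falls were Klrg1, a receptor of differentiated T and NK cells (at least 4.04-fold), Nacc2 (at least 3.59-fold), the lysosomal channel Mcoln3 (at least 2.35-fold), Zfp982 (at least 2.38-fold), Bcar3 (at least 4.002-fold), the desaturase Scd1 (3.55-fold), Card19 (at least 2.46-fold) and Elac1 (3.12-fold). Il2ra was 1.76-fold lower (log2 difference -0.82 ± 0.23). Calls for Il2ra ended without wild-type resting array 1 or 2 or knockout resting array 1 or 3 (adjusted p = 0.0701, 0.0782, 0.0968 and 0.0582), and for Scd1 without wild-type resting array 1 or 2 or knockout resting array 1, 2 or 3 (0.0663, 0.137, 0.0753, 0.0524 and 0.0784). A fit on the 2 groups alone ended the calls of Aldh1a1, Aurkb, Card19, Ccne1, Ccne2, Cldn13, Ctsg, Elac1, Gclm, Il2ra, Klf1, Klrg1, Mcm2, Mcoln3, Prtn3, Scd1 and Slc4a1 (adjusted p = 0.0597 to 0.138). The erythroid covariate ended these 17 and those of Bcar3 and Esrra (0.0540 to 0.993). Of these, Bcar3 (-2.09 with the covariate, -2.07 without), Esrra (-0.86, -0.87), Klrg1 (-3.11, -2.80), Mcoln3 (-1.81, 0.824 of that without), Il2ra (-0.65, -0.82) and Scd1 (-1.41, -1.83) kept at least 0.77 of their log2 difference, while the median SE of the changed genes rose from 0.126 to 0.226. Aldh1a1 (0.57), Aurkb (0.02), Card19 (-0.10), Ccne1 (0.19), Ccne2 (0.99), Cldn13 (0.45), Ctsg (0.30), Elac1 (-0.19), Gclm (0.37), Mcm2 (0.05) and Slc4a1 (1.38) kept at most 0.383 of it, and Klf1 (-0.90) and Prtn3 (-1.16) reversed; Klf1 and Slc4a1 are part of that covariate. With the myeloid and neutrophil covariate Aurkb (1.15), Card19 (-1.08), Ccne1 (1.08), Elac1 (-1.27), Il2ra (-0.61), Klf1 (3.78), Mcm2 (0.49), Prtn3 (3.11) and Scd1 (-1.84) did not pass (0.0569 to 0.198), with at least 0.582 of their differences. Il2ra and Scd1 did not pass with no filter (0.0509 and 0.0729), nor Scd1 on the arrays numbered 2 and 3 (0.0600). Of 19 fatty acid oxidation genes 0 passed (adjusted p = 0.402 for the list, direction up, with a median of -0.02 and a mean of 0.03). Cpt1a and Cycs differed by 0.28 ± 0.29 and 0.00 ± 0.10 and did not pass. Leaving out 1 array moved some called fitted folds by over 1.5 times, here as log2 differences. Aldh1a1 was 5.17 (from 4.25), Cldn13 5.51 (from 4.68), Ctsg 5.48 (from 4.55), Klf1 5.49 (from 4.32), Prtn3 6.17 (from 4.79), Rhd 6.23 (from 5.47) and Slc4a1 6.09 (from 5.09) without wild-type resting array 1. Aldh1a1 was 3.66, Cldn13 3.66, Ctsg 3.94, Klf1 2.75, Prtn3 4.02 and Slc4a1 4.48 without wild-type resting array 2. Prtn3 was 4.17 without wild-type resting array 3. Aldh1a1 was 3.61, Aurkb 1.25 (from 1.97), Ccne2 1.98 (from 2.58), Cldn13 3.98, Ctsg 3.72, Prtn3 3.53 and Rhd 4.88 without knockout resting array 1. Without knockout resting array 2 Klrg1 was -3.43 (from -2.80), and without array 2 or 3 Prtn3 was 5.42 or 5.41.

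Of 6873 genes, 1308 differed between the resting genotypes, 463 higher and 845 lower in knockout cells, and 252 at least 2-fold. The median over all tested genes was -0.11, and with each array shifted to the same median the share of changed genes that were higher went from 35.4% to 46.0%. The count fell to 737, 612 and 848 without wild-type resting array 2, wild-type resting array 3 and knockout resting array 1, to 176 in a fit on the 2 groups alone, and to 485 and 214 with the myeloid and neutrophil or the erythroid marker mean of each array as a covariate, chosen after seeing the data. It was 2379 with array weights, and the comparison crosses the dap split.

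**Figure D2:**
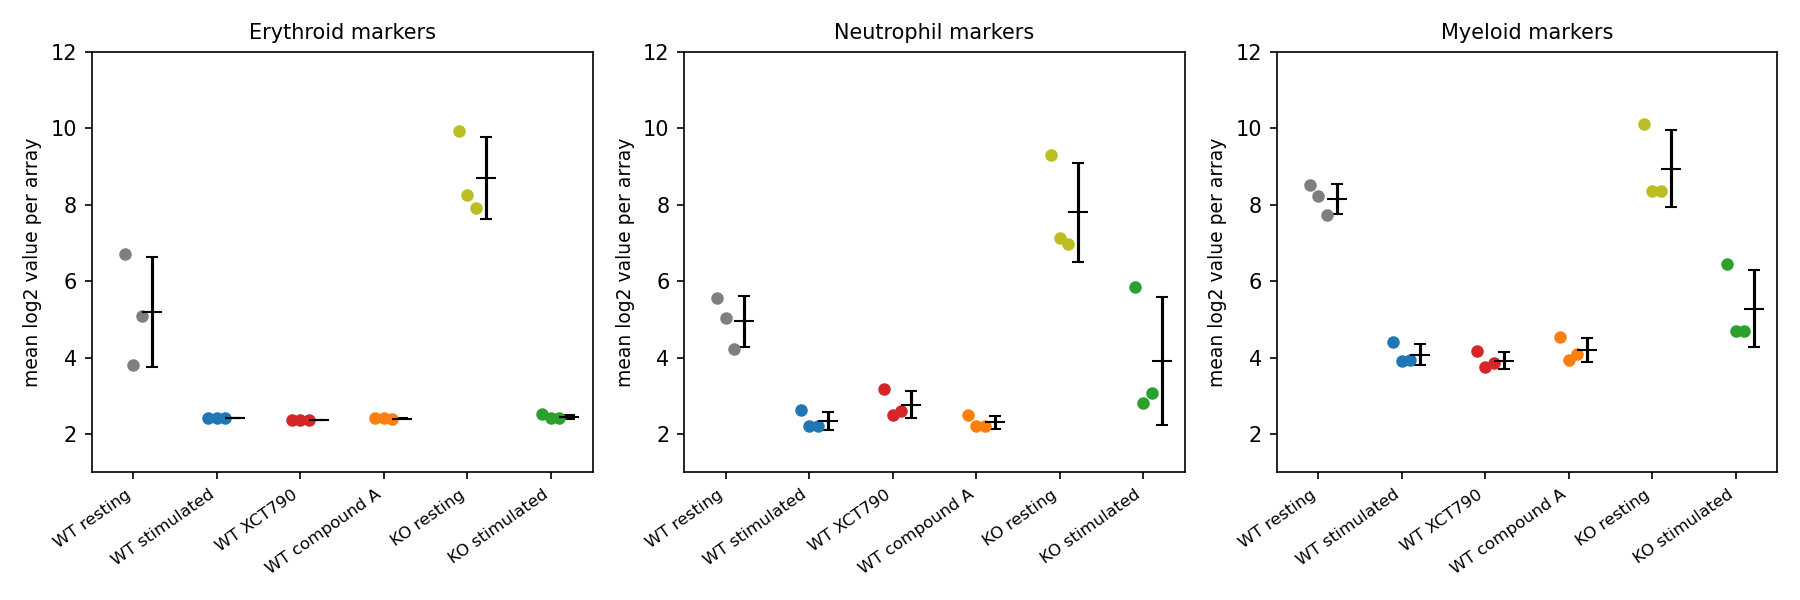
Mean log2 value per array (y axis) of the erythroid, neutrophil and myeloid marker lists in the 6 groups; points are arrays, bars the mean and SD (n = 3). Erythroid markers average 8.69 in resting knockout and 5.19 in resting wild-type arrays and lie near 2.4 after stimulation in both genotypes.

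Stimulated knockout against stimulated wild-type cells asks which transcripts of activated cells differ without ERRα. Knockout cells carried more Il6 (at least 7.80-fold; adjusted p = 7.43e-04), Il17a, the Th17 cytokine (7.42-fold; adjusted p = 0.0111), Il3 (at least 1.73-fold; adjusted p = 0.0155) and Il12rb2 (at least 1.52-fold; adjusted p = 2.10e-04). They carried less of the circadian transcription factor Npas2 (at least 3.49-fold; adjusted p = 3.79e-08). Npas2 read 2.24 ± 0.00 (SD, n = 3) in resting and 5.80 ± 0.37 in stimulated wild-type cells, and 2.88 ± 0.19, 2.28 ± 0.02 and 2.39 ± 0.13 in stimulated knockout, XCT790 and compound A cells. The mitochondrial genes Chchd10 (2.11-fold), Slc25a23 (1.85-fold) and Dlat, of the pyruvate dehydrogenase complex (1.40-fold), fell. Other falls were Zfp982 (at least 3.09-fold), Rell1 (at least 2.35-fold), Rab2b (2.13-fold) and Dstyk (1.89-fold), and other rises the nuclear RNA Malat1 (7.15-fold), Cntrl (at least 8.44-fold), Rab4a (at least 3.62-fold) and Wdfy1 (8.32-fold). The lysozymes Lyz2 (at least 19.1-fold; adjusted p = 0.0335) and Lyz1 (34.0-fold; adjusted p = 0.0432), made by myeloid cells, were the largest fitted rises. Il2, Ifng and Il2ra differed by -0.44 ± 0.28, 0.22 ± 0.34 and 0.11 ± 0.23 and did not pass (adjusted p = 0.478, 0.801 and 0.870), nor did Cpt1a (1.15 ± 0.29; adjusted p = 0.0562, 0.0314 with the array number as a block and 0.0158 without wild-type stimulated array 1). Both Il2 and Cpt1a passed with array weights (0.00683 and 0.00134) and on the arrays numbered 2 and 3 (0.00660 and 0.0102), and Cpt1a with arrays shifted to a common median (0.0497) and a trended and robust prior (0.0427). Without wild-type stimulated array 2 the adjusted p was 0.0676 for Il17a, 0.104 for Il3, 0.179 for Lyz2, 0.196 for Lyz1, 0.131 for Rab2b, 0.121 for Slc25a23 and 0.0681 for Dstyk. Without wild-type stimulated array 3 it was 0.132 for Lyz2, 0.172 for Lyz1, 0.118 for Rab2b and 0.0691 for Slc25a23. Without knockout stimulated array 1 it was 0.144 for Lyz2, 0.174 for Lyz1, 0.116 for Rab2b and 0.115 for Slc25a23. It was 0.0654 for Il3 and 0.0728 for Slc25a23 without wild-type stimulated array 1, 0.0509 for Il3 and 0.0616 for Lyz1 without knockout stimulated array 2, and 0.0659 for Rab2b without knockout stimulated array 3. Some called fitted log2 differences moved by over 1.5 times as folds. Lyz1 was 6.22 (from 5.09) and Lyz2 6.03 (from 5.13) without wild-type stimulated array 1, and Lyz1 4.41 without array 3. Il17a was 2.14 (from 2.89), Il6 2.79 (from 3.43), Lyz1 3.88 and Lyz2 3.86 without knockout stimulated array 1. Lyz2 was 5.82 and 5.73 without knockout stimulated arrays 2 and 3, and Lyz1 5.72 without array 3.

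Few members of any list passed between stimulated knockout and wild-type cells. Cytokines and chemokines rose in 3 of 21 (4 adjusted over the list alone; camera adjusted p = 0.00382; 0.458 with an estimated correlation): Il6, Il17a and Il3. Th17 genes rose in 1 of 7, Il17a (4 adjusted over the list alone; adjusted p = 2.29e-06; 0.276 with an estimated correlation), and Th1 genes in 1 of 9, Il12rb2 (2 adjusted over the list alone; adjusted p = 3.97e-04; 0.458 with an estimated correlation). Type I interferon genes rose in 1 of 15, Usp18 by 1.48 ± 0.33 (log2, SE), a call that ended without wild-type stimulated array 1, 2 or 3 or knockout stimulated array 1 (adjusted p = 0.0652, 0.177, 0.0642 and 0.0638). Adjusted over the list alone 4 interferon genes rose, and the list had a median of 1.15 (adjusted p = 6.38e-09, and 0.458 with an estimated correlation). Of the reported ERRα targets 1 of 19 fell, Esrra itself (1 adjusted over the list alone; median -0.13; adjusted p = 0.00382; 0.458 with an estimated correlation). Of 55 mitochondrial ribosomal proteins 0 fell (0 adjusted over the list alone; median -0.12; adjusted p = 8.28e-04; 0.527 with an estimated correlation). Tricarboxylic acid cycle genes fell in 1 of 22, Dlat (1 adjusted over the list alone; adjusted p = 0.00388; 0.467 with an estimated correlation). Mitochondrial biogenesis genes fell in 1 of 25, the mitochondrial RNA polymerase Polrmt (1 adjusted over the list alone; adjusted p = 0.0121; 0.458 with an estimated correlation). Polrmt differed by -0.38 ± 0.08, and the call ended without wild-type stimulated array 2 or 3 or knockout stimulated array 1 or 2 (adjusted p = 0.135, 0.0759, 0.101 and 0.0771). ATP synthase fell in 1 of 16, Atp5o (1 adjusted over the list alone; adjusted p = 0.0319, 0.0601 with the array number as a block; 0.527 with an estimated correlation). Atp5o differed by -0.27 ± 0.06, and its call ended without any 1 of the 6 arrays (adjusted p = 0.0689, 0.196 and 0.0825 without wild-type, 0.143, 0.0806 and 0.0655 without knockout stimulated arrays 1, 2 and 3). Markers of NK cells rose in 1 of 13 (adjusted p = 7.47e-06; 0.276 with an estimated correlation), of CD8 T cells in 1 of 7 (0.0319, 0.0910 with the array number as a block; 0.458 with an estimated correlation) and of dendritic cells in 0 of 8 (0.0148; 0.458). Adjusted over the list alone 3, 3 and 0 rose, and 1 CD8 marker fell. Myeloid markers rose in 3 of 16 (4 adjusted over the list alone; adjusted p = 5.53e-05; 0.458 with an estimated correlation). They averaged 5.28 ± 1.00 (SD, n = 3) in stimulated knockout and 4.08 ± 0.276 in stimulated wild-type arrays, with 6.44 on the highest knockout array. A fit on the 2 groups alone ended the calls of Il6, Il17a, Il3, Dlat, Dstyk, Lyz1, Lyz2, Polrmt, Atp5o, Rab2b, Slc25a23 and Usp18 (adjusted p = 0.0660 to 0.163). No filter ended those of Lyz1, Lyz2, Rab2b, Slc25a23 and Usp18 (0.0571 to 0.0953), the myeloid and neutrophil covariate those of Il17a (2.28), Atp5o (-0.25), Lyz1 (2.89), Lyz2 (2.90), Polrmt (-0.31), Rab2b (-0.63), Slc25a23 (-0.54) and Usp18 (1.15, log2; adjusted p = 0.0547 to 0.137), and the arrays numbered 2 and 3 those of Il17a, Atp5o, Dstyk and Slc25a23 (0.0610 to 0.0713). Atp5o also did not pass with arrays shifted to a common median (0.0563), nor Rab2b with the mean of all probe sets (0.0735). Of 46 lists, 18 passed with camera and a preset correlation, 0 with an estimated one and 0 with fry. In all 150 genes differed, 109 higher and 41 lower. The count was 66, 77, 85 and 99 without wild-type stimulated array 2, wild-type stimulated array 3, knockout stimulated array 1 and knockout stimulated array 2, 248 with the mean of all probe sets of a gene and 1639 with array weights. It was 432 on the arrays numbered 2 and 3 alone, chosen after seeing the data, and the comparison crosses the dap split.

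XCT790 asks what a chemical inverse agonist of ERRα does to wild-type cells during activation. Treated cells carried more of the ATF4 and HIF target genes, less of the mitochondrial respiratory genes and less interferon gamma, while Il2 and Il2ra did not pass. Ifng was 34.8-fold lower, at 6.43 ± 0.42 (SD, n = 3) against 11.55 ± 0.36 (adjusted p = 1.77e-08); Il2 differed by -0.32 ± 0.28 (adjusted p = 0.330) and Il2ra by -0.47 ± 0.23 (adjusted p = 0.0842, 0.0493 with the array number as a block, 0.0376 with stimulated knockout cells as the reference, and 0.0293 and 0.0495 without XCT790 arrays 2 and 3). The heat shock proteins Hspa1b (98.6-fold) and Hspa1a (at least 32.6-fold), the pseudokinase Trib3 (at least 38.8-fold), the angiogenic factor Vegfa (at least 21.2-fold), Ndrg1 (22.9-fold), Abca1 (at least 14.8-fold), the chemokine receptor Cxcr4 (21.4-fold) and Cntrl (at least 13.8-fold) had the largest fitted rises. Crabp2 (at least 63.4-fold), Myo6 (at least 28.4-fold), protein S Pros1 (at least 28.7-fold), Cxcl9 (at least 24.8-fold), granzyme A Gzma (at least 14.8-fold), Usp18 (at least 28.3-fold) and the interleukin-12 receptor chain Il12rb1 (30.0-fold) the largest fitted falls. Leaving out 1 array moved 2 called log2 differences by over 1.5 times as folds. Hspa1a was 5.97 (from 6.60) and Ifit1 -3.81 (from -2.98) without XCT790 array 1. Hspa1a was 7.20 without XCT790 array 2. In all 4534 of 6873 genes changed, 1997 upward and 2537 downward, 1449 of them at least 2-fold.

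Targets of ATF4, the transcription factor of the integrated stress response, rose in 18 of 19 and fell in 0 with XCT790 (adjusted p = 2.53e-09, and 0.00536 with an estimated correlation), among them Sesn2 (4.73-fold), Chac1 (at least 6.23-fold) and Cebpg (4.04-fold). HIF targets rose in 15 of 16 (adjusted p = 1.37e-09, and 0.0860 with an estimated correlation), with Kdm3a 5.18-fold and P4ha1 5.99-fold higher. Glycolysis genes rose in 10 of 16 and fell in 1 (adjusted p = 0.00136, and 0.318 with an estimated correlation); the glucose transporters Slc2a3 and Slc2a1 were 10.8-fold and 3.63-fold higher and the lactate exporter Slc16a3 at least 4.13-fold. Liver X receptor targets rose in 6 of 9 and fell in 1 (adjusted p = 0.0180, and 0.215 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 19 (adjusted p = 4.48e-05, and 0.318 with an estimated correlation), with Pmvk 5.99-fold and Fdps 3.88-fold lower. Complex I fell in 30 of 33 and rose in 1 (adjusted p = 2.98e-08, and 0.318 with an estimated correlation), with Ndufa5 2.69-fold lower. ATP synthase fell in all 16 genes (adjusted p = 1.35e-05, and 0.254 with an estimated correlation), with Atp5e 1.78-fold lower. The tricarboxylic acid cycle fell in 20 of 22 (adjusted p = 4.48e-05, and 0.318 with an estimated correlation), with Suclg1 2.72-fold lower. Mitochondrial ribosomal proteins fell in 53 of 55 (adjusted p = 3.88e-14, and 0.215 with an estimated correlation), with Mrpl4 3.10-fold lower. Adjusted over the list alone, 54 mitochondrial ribosomal proteins fell, and the other 8 lists kept their counts.

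Fatty acid oxidation genes fell in 12 of 19 and rose in 1 with XCT790 (adjusted p = 0.0180, and 0.386 with an estimated correlation). The isomerase Eci1 was 5.08-fold and Acadm 1.49-fold lower, and the 1 that rose was Cpt1a (3.92-fold). The reported ERRα targets fell in 13 of 19 and rose in 2 and did not pass as a list (adjusted p = 0.0797; median -0.45). Sdhb and Fh1, of the tricarboxylic acid cycle, were 1.75-fold and 2.39-fold lower, and Vegfa was among those that rose. Cytokines and chemokines fell in 15 of 21 and rose in 2 (adjusted p = 0.0114, and 0.446 with an estimated correlation), with Il4 at least 9.03-fold and Ccl1 at least 11.4-fold lower. Type I interferon genes fell in 10 of 15 (adjusted p = 0.0360, and 0.697 with an estimated correlation), with Ifit1 7.87-fold lower. Markers of NK cells fell in 4 of 13, of CD8 T cells in 4 of 7 with 1 that rose and of dendritic cells in 5 of 8 with 1 that rose; none of the 3 lists passed with the preset (adjusted p = 0.196, 0.193 and 0.219), and all 3 did with fry (2.46e-05, 1.04e-05 and 6.58e-04). Cell cycle genes fell in 17 of 25 and rose in 2 (adjusted p = 0.00419, and 0.642 with an estimated correlation): the replication genes Mcm2 (5.25-fold) and Mcm4 (4.29-fold) fell and the cell cycle inhibitor Cdkn1b (4.54-fold) rose. The counts adjusted over the list alone were the same for these 8 lists. The 3 XCT790 arrays also stood apart from the other 15 in quality controls: the actin 3' minus 5' difference was 0.691 to 0.801 against at most 0.576, the 5' probe set of the thr control RNA 3.36 to 4.36 against at most 3.01, and 18S ribosomal RNA 13.2 to 13.4 against at most 12.8. Treatment and these controls go together in every comparison with XCT790. The comparison crosses the dap split. Against stimulated knockout cells, on the same side of it and chosen after seeing the data, XCT790 changed 4482 genes, 3996 of them in the direction called against wild-type cells with the same XCT790 arrays; ATF4 targets rose in 17 of 19, HIF targets in 15 of 16, and complex I fell in 29 of 33. Markers of NK cells fell in 8 of 13 there (camera adjusted p = 0.0123, and 0.337 with an estimated correlation). This list also passed between stimulated knockout and wild-type cells, so the knockout reference enters this fall. Of the genes named, Cntrl (0.71, from 4.34) did not pass there (0.160). Apart from Esrra, the other log2 differences moved by over 1.5 times as folds were Cpt1a (0.82, from 1.97), Cxcr4 (3.68, from 4.42), Hspa1b (5.88, from 6.62), Crabp2 (-7.02, from -7.69), Cxcl9 (-7.64, from -5.62), Gzma (-6.35, from -5.12), Ifit1 (-4.12, from -2.98), Myo6 (-7.38, from -6.58) and Usp18 (-6.48, from -5.01).

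Compound A is the other inhibitor, at the same dose and time. Treated cells carried less Il2 and Ifng, less of the ribosome biogenesis genes and more Cpt1a than stimulated cells. Cpt1a was 5.37-fold higher (adjusted p = 4.40e-05), Ifng 3.15-fold lower (adjusted p = 0.00207) and Il2 1.90-fold lower (adjusted p = 0.0201), and Il2ra did not pass, with a difference of -0.24 ± 0.23 (adjusted p = 0.474). The Il2 call ended without wild-type stimulated array 2 or 3 or compound A array 1 (adjusted p = 0.0605, 0.0545 and 0.0886). The largest fitted falls were the chemokine Ccl1 (at least 11.4-fold), Crabp2 (20.0-fold), Gzma (9.67-fold), alpha-fetoprotein Afp (9.35-fold), Tacc2 (7.06-fold), the adenylate kinase Ak4 (6.29-fold), the ubiquitin-like Ubd (at least 3.97-fold) and Npas2 (at least 3.49-fold). The largest fitted rises were Malat1 (13.1-fold), Cntrl (at least 10.3-fold), Hspa1b (9.84-fold), Hspa1a (at least 3.31-fold), Zbtb7a (8.64-fold), the chromatin remodeller Atrx (8.31-fold), the demethylase Kdm5a (6.95-fold) and Cfap97 (6.08-fold). Called fitted log2 differences moved by over 1.5 times as folds for 4 genes. Ubd was -2.87 (from -3.57) without wild-type stimulated array 1. Afp was -3.82 (from -3.22), Hspa1a 4.60 (from 3.30) and Hspa1b 4.33 (from 3.30) without compound A array 1. Hspa1a was 2.58 and Hspa1b 2.69 without compound A array 2. Hspa1a did not pass in a fit on the 2 groups alone (adjusted p = 0.0634). Of 6873 genes, 2283 changed, 999 upward and 1284 downward, 257 of them at least 2-fold, and 4048 changed with array weights.

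With compound A, ribosome biogenesis fell in 26 of 33 (26 adjusted over the list alone; adjusted p = 1.00e-09; 0.582 with an estimated correlation), with Nip7 1.54-fold lower. Mitochondrial ribosomal proteins fell in 35 of 55 (38 adjusted over the list alone; adjusted p = 7.50e-10; 0.582 with an estimated correlation), with Mrpl12 1.54-fold lower. Cytokines and chemokines fell in 11 of 21 and rose in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.00510; 0.879 with an estimated correlation). Glycolysis genes fell in 5 of 16, the same adjusted over the list alone (adjusted p = 0.0259; 0.879 with an estimated correlation), with Pfkl 1.83-fold, Pgam1 1.48-fold and Ldha 1.32-fold lower. Slc2a1 was 1.43-fold lower, a call that ended without wild-type stimulated array 1 or 3 (adjusted p = 0.0857 and 0.0724) or compound A array 1, 2 or 3 (0.0510, 0.0627 and 0.0643) or with no filter (0.0526). Tricarboxylic acid cycle genes fell in 6 of 22, the same adjusted over the list alone (adjusted p = 0.0259; 0.879 with an estimated correlation), with Dlat 1.49-fold lower. Genes of quiescent and naive T cells rose in 11 of 18 and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 7.46e-05; 0.582 with an estimated correlation), including the egress receptor S1pr1 (4.04-fold) and the transcription factor Lef1 (2.54-fold). Fatty acid oxidation genes rose in 4 and fell in 2 of 19, the same adjusted over the list alone, and did not pass as a list (adjusted p = 0.393); the acyl-CoA dehydrogenases Acadl (1.80-fold) and Acadvl (1.49-fold) rose with Cpt1a. The reported ERRα targets fell in 3 of 19 (1 adjusted over the list alone) and did not pass as a list (adjusted p = 0.194). The comparison crosses the dap split. Against stimulated knockout cells compound A changed 1792 genes, 1354 of them in the direction called against wild-type cells with the same compound A arrays, and tricarboxylic acid cycle genes fell in 0 of 22 (adjusted p = 0.412). Ribosome biogenesis fell in 18 of 33 (adjusted p = 5.13e-09, and 0.437 with an estimated correlation), mitochondrial ribosomal proteins in 22 of 55 with 1 that rose (4.76e-07 and 0.637), and cytokines in 11 of 21 with 1 that rose (1.92e-06 and 0.437). Quiescence genes rose in 7 of 18 and fell in 1 (0.0161 and 0.637), and glycolysis fell in 3 of 16 (0.0429 and 0.645). Type I interferon genes fell in 6 of 15 there (7.05e-05 and 0.637). Markers of other cells fell with the cytokines: NK cells in 4 of 13 (0.000262 and 0.437), CD8 T cells in 2 of 7 (0.0144 and 0.637) and dendritic cells in 4 of 8 (0.0165 and 0.637). Against wild-type cells these fell in 3, 3 and 2 and did not pass with the preset (0.244, 0.167 and 0.353). Of the genes named, Atrx (0.32, from 3.06), Cfap97 (0.24, from 2.60), Cntrl (0.29, from 3.93), Dlat (-0.09), Il2 (-0.49), Kdm5a (0.41, from 2.80), Lef1 (0.44, from 1.34), Slc2a1 (-0.28) and Zbtb7a (0.33, from 3.11) did not pass there (0.0831 to 0.658). Malat1 was 0.88 there (from 3.72), Cpt1a 1.28 (from 2.43), S1pr1 0.91 (from 2.01), Npas2 -0.49 (from -3.41, under log2 4 in knockout cells), Ak4 -2.05 (from -2.65), Crabp2 -3.66 (from -4.32), Hspa1b 2.55 (from 3.30), Gzma -4.50 (from -3.27) and Ubd -5.66 (from -3.57).

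**Figure D3:**
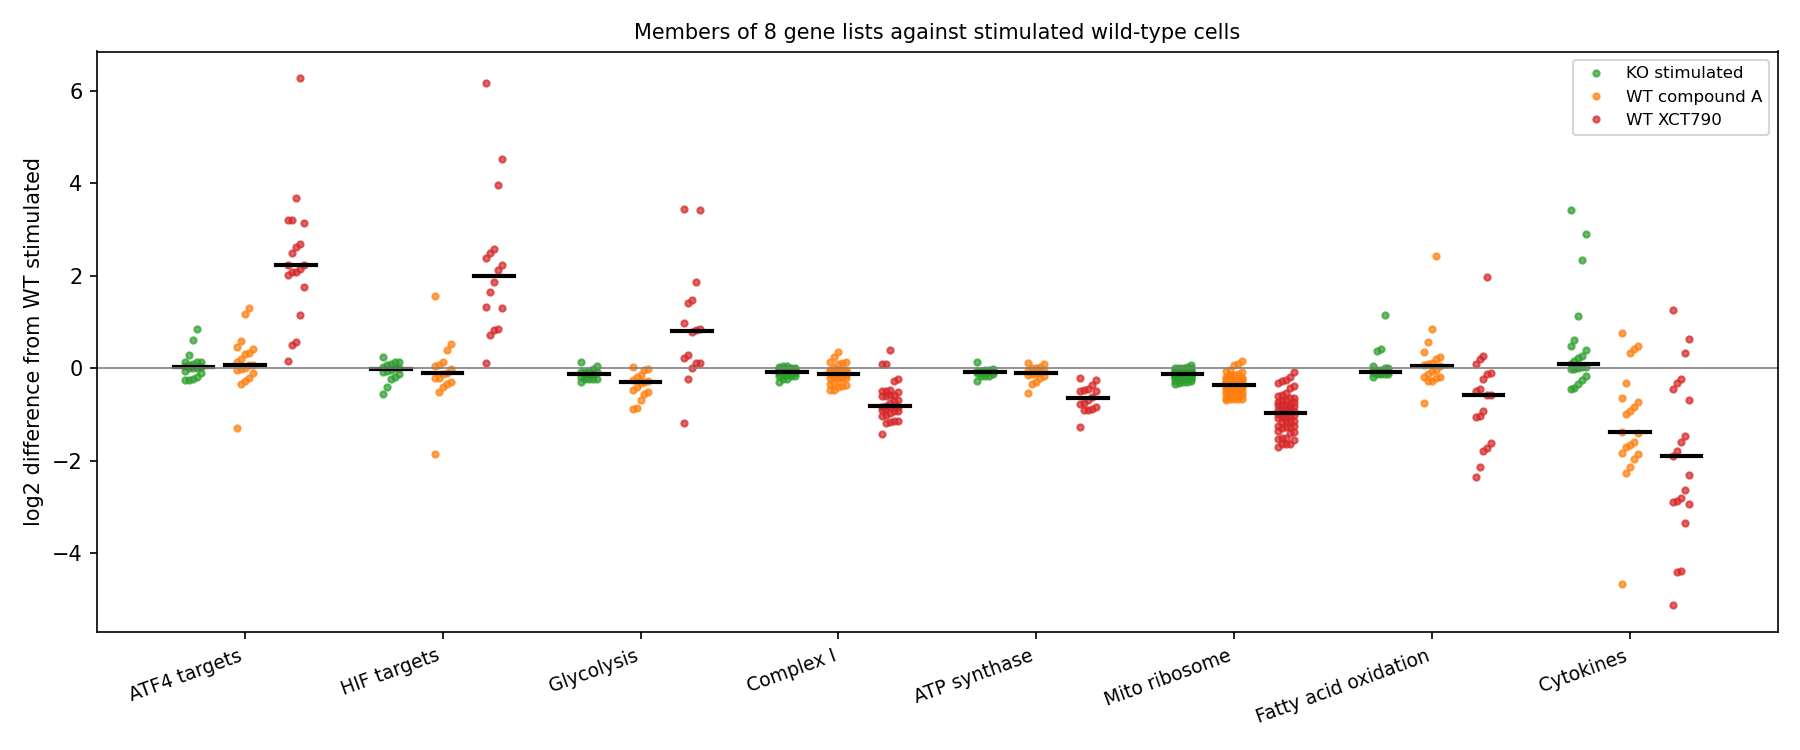
Log2 difference from stimulated wild-type cells (y axis) of each tested member of 8 gene lists in stimulated knockout, compound A and XCT790 cells; points are genes, black bars list medians, and genes near the floor enter with their fitted difference. The XCT790 medians are 2.22 for ATF4 targets and -0.81 for complex I.

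XCT790 against compound A compares the inhibitors at the same dose and time, on one side of the dap split. The XCT790 arrays still differed from the compound A arrays in the quality controls given above, where compound A arrays read 0.418 to 0.529 for actin, 2.64 to 3.01 for thr and 11.01 to 12.4 for 18S. HIF and ATF4 targets and glycolysis genes were higher with XCT790, and respiratory and fatty acid oxidation genes lower. All 16 HIF targets (adjusted p = 4.69e-14, and 0.0199 with an estimated correlation) and all 19 ATF4 targets (adjusted p = 2.82e-12, and 0.00145 with an estimated correlation) were higher with XCT790, the same adjusted over the list alone. Vegfa was at least 21.2-fold higher, the mitophagy receptor Bnip3 18.1-fold, Ak4 32.9-fold, Slc16a3 at least 4.13-fold, Slc2a1 5.18-fold, Abca1 at least 14.9-fold, Trib3 31.7-fold, the transcription factor Maff at least 12.0-fold and Spin4 16.0-fold. Myo6 was at least 20.3-fold lower, Pros1 at least 14.4-fold, the protease Prss16 at least 9.67-fold, the inhibitory receptor Lag3 22.4-fold, Usp18 at least 15.42-fold, Cxcl9 at least 7.98-fold and the nucleic acid sensor Zbp1 11.3-fold. Ifng was lower by a log2 difference of -3.46 ± 0.34 (SE). Glycolysis genes were higher in 12 of 16 and lower in 1 (13 and 1 adjusted over the list alone; adjusted p = 7.10e-07, and 0.101 with an estimated correlation). Complex I was lower in 30 of 33 (adjusted p = 5.72e-11, and 0.164 with an estimated correlation), ATP synthase in 16 of 16 (adjusted p = 1.01e-06, and 0.149 with an estimated correlation) and fatty acid oxidation in 15 of 19 (adjusted p = 2.14e-05, and 0.149 with an estimated correlation; Etfb 3.06-fold). Counts adjusted over the list alone were the same for complex I, ATP synthase and fatty acid oxidation. Cpt1a, Il2, Il2ra and Cycs did not pass, with differences of -0.45 ± 0.29, 0.61 ± 0.28, -0.24 ± 0.23 and 0.01 ± 0.10 (SE; adjusted p = 0.206, 0.0818, 0.418 and 0.941). Il2 passed with the array number as a block (adjusted p = 0.0313), with array weights (2.16e-04) and on the arrays numbered 2 and 3 (0.00166). Moved by over 1.5 times as folds were these log2 differences. Lag3 was -3.60 and -5.18 (from -4.49) without XCT790 arrays 1 and 2. Spin4 was 5.01 and Trib3 4.39 (from 4.99) without compound A array 1. In all 3617 genes differed, 1707 higher and 1910 lower with XCT790, and 764 at least 2-fold.

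Against resting wild-type cells, both inhibitor groups carried the transcripts of activated T cells. Il2 was 88.8-fold higher with XCT790 and 58.4-fold with compound A, and Il2ra 9.94-fold and 11.7-fold. Ifng was 2.46-fold lower than in resting cells with XCT790 and 4.49-fold higher with compound A. T cell activation markers rose in 12 of 15 with each inhibitor and fell in 1 with XCT790 and 0 with compound A, the same adjusted over the list alone (adjusted p = 1.14e-04 and 7.96e-05; 0.139 and 0.124 with an estimated correlation), and ribosome biogenesis genes in all 33 with each inhibitor (adjusted p = 4.94e-12 and 4.29e-14; 0.139 and 0.124 with an estimated correlation). Tg (at least 54.8-fold), Akr1c18 (at least 53.6-fold), Lad1 (at least 93.7-fold), Ccl4 (at least 72.5-fold) and Cdkn1a (at least 46.2-fold) were among the genes that rose with XCT790, and Ccl22 (at least 100.2-fold), Tg (at least 83.8-fold), Lad1 (at least 117-fold), Lag3 (at least 51.7-fold) and Ccl4 (at least 42.6-fold) with compound A; bounds against log2 4 give no rank. Csf1r, Car1 and Vcam1 fell at least 77.4-fold with each, and the immunoglobulin gene Igha 407-fold and 264-fold; Slc40a1 (at least 58.2-fold) also fell with XCT790 and Igkv15-103 (at least 338-fold) with compound A. The log2 difference of Igha from resting cells was -9.73 and -7.77 (from -8.67) without XCT790 arrays 1 and 2, and -8.87 and -7.40 (from -8.05) without compound A arrays 1 and 3. XCT790 changed 4940 and compound A 4788 of 6873 genes, and these comparisons cross the dap split.

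An activation score was built from the 270 genes that rose and 460 that fell at least 4-fold with stimulation in knockout arrays. It was read on the 12 wild-type arrays, which did not enter those folds. Set to 0 in resting and 1 in stimulated wild-type cells, it was 0.810 ± 0.0222 (SD, n = 3) with XCT790 and 0.863 ± 0.0023 with compound A. Every inhibitor array lay below every stimulated wild-type array and above every resting one. The two-sided exact permutation p was 0.1 for each comparison, the smallest that 3 against 3 allow. These comparisons cross the dap split, and the 460 include markers of other cells.

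**Figure D4:**
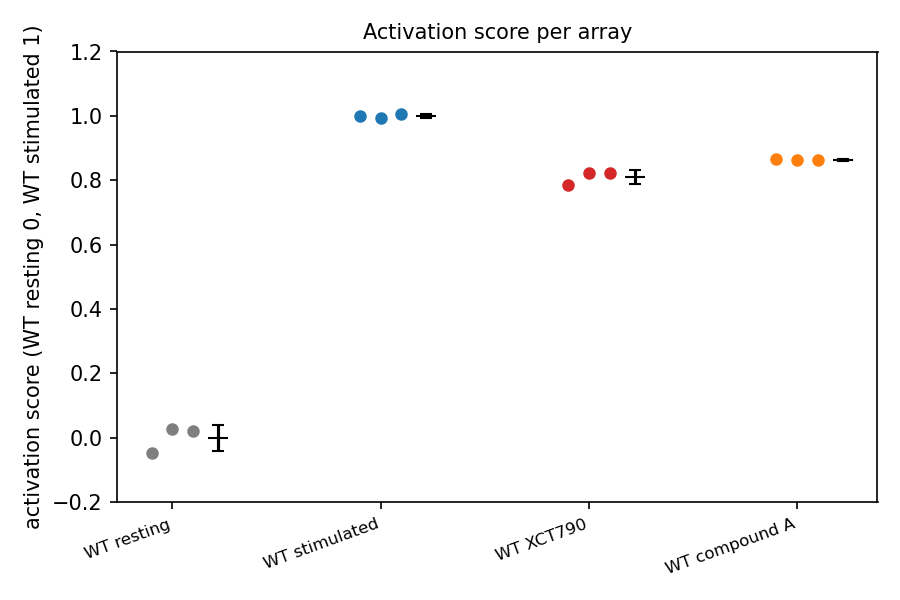
Activation score (y axis, no unit; wild-type resting 0, wild-type stimulated 1) per array in the 4 wild-type groups; points are arrays, bars the mean and SD (n = 3). The inhibitor groups average 0.810 and 0.863.

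Across 6873 genes, not independent replicates, log2 changes with XCT790 and compound A against stimulated wild-type cells correlated with r = 0.663 (jackknife SE 0.0262). With stimulated knockout cells as the reference, chosen after seeing the data, r was 0.680. Knockout and XCT790 changes correlated with r = 0.134 (SE 0.0750), and knockout and compound A changes with r = 0.275 (SE 0.166). Each pair shares its wild-type reference arrays, so calls are not independent, and crosses the dap split. From the shared reference alone, 100 simulated data sets gave mean r of 0.496, 0.497 and 0.501. Covariances were 0.302, 0.0445 and 0.0476, above the simulated means by 0.281, 0.0238 and 0.0267. The split, absent from the simulation, can itself give excess covariance and shared calls. The inhibitors raised 757 genes in common and lowered 1065, against 290.3 and 474 for independent calls, and moved 123 in opposite directions. Of the 109 genes higher in stimulated knockout cells, 75 were also higher with XCT790 and 83 with compound A, against 31.7 and 15.8 for independent calls. Of the 41 lower, 27 and 29 were lower, against 15.1 and 7.66, and 25 and 4 of the 150 moved the opposite way. Simulated data gave at most 1 shared call, but hardly any gene is called there, so this sets no baseline. The 68 genes higher in all 3 settings include Malat1 and Cntrl, which follow the dap split.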

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

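Chosen after the results were seen were the fits with marker covariates and the sorting of the interaction splits. So were the tests of erythroid RNA on the genes higher and on those lower in resting knockout cells. The other tests here were written before their value was seen.

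The 5' probe set of the dap control RNA, which is no part of the comparisons, differed by 2.89 between the 6 untreated wild-type arrays and the other 12. Of the 109 genes higher in stimulated knockout cells, 68 were also higher with both inhibitors, though all 3 comparisons share the stimulated wild-type arrays, and 55 genes were higher in all of resting knockout, stimulated knockout, XCT790 and compound A cells. For the 35 of these 55 with other probe sets, the other probe sets moved by a median of 0.290 of the shift of the probe set used, below the 0.910 to 1.21 of random draws of genes induced by stimulation. Another labelling run with longer labelled transcripts in the 12 arrays is a candidate explanation for these genes as a set, but 15 of the 35 had ratios of at least 0.5, among them Malat1 (0.771), Akap9 (0.809), Atrx (0.942) and Nr2c2 (1.14), and Cntrl has no other probe set. Loss of ERRα activity stays open, since the dap split parts the same arrays. Of the 18 genes induced by stimulation and lower in stimulated knockout, XCT790 and compound A cells, like Npas2, 6 had other probe sets. Their ratio, 0.873, lay inside the -0.42 to 1.03 of the draws. A labelling run and loss of ERRα activity cannot be told apart for the 18.

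Resting knockout arrays differed from resting wild-type arrays in 1308 genes. RNA of erythroid precursors or other cells may account for most of the shift of the 463 higher genes. With the erythroid marker mean as a covariate their median shift was 0.264 of its value without it, the 5 markers left out. Still, 75 passed. Erythroid and neutrophil markers both peaked on array 1 of each resting genotype, so the covariate may stand for either. For the 845 lower genes the ratio was 0.693 and for all 1303 genes without the markers 0.574, and with the covariate the median shift of the 1308 went from 0.51 to 0.29 while the median SE rose from 0.126 to 0.226, so 120 passed and the others lost their call partly to the larger error. Ermap, 1 of the 5 markers, read 11.03 ± 1.05 (SD, n = 3) in resting knockout and 8.13 ± 1.48 in resting wild-type arrays, in cells purified by negative selection, and the markers averaged 2.45 and 2.42 after stimulation. The labelling run as the whole cause is argued against by the stimulated arrays, where the median ratio of the knockout shift to the resting shift was 0.230 (quartiles 0.00 to 0.486); genotype itself stays open.

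The response to stimulation differed between genotypes in 62 genes by the interaction test. Of 100 splits of the 12 arrays, 8 gave as many genes, the real one included, a share not under 0.05. The highest gave 490, and 302 among the 15 splits that part as many pairs of equally numbered arrays. The 7 other splits with as many keep the genotypes of 1 state whole, 6 at rest and 1 stimulated, and so carry the genotype difference of that state into the interaction. The 80 splits that mix the genotypes in both states gave at most 2, and mixing also widens the spread within the groups, so the splits do not tell whether chance gave the 62. With the array number as a block 123 passed.

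The fitted response was more upward in knockout cells for Il6 (3.44), Klrg1 (2.80), Nacc2 (2.29), Mcoln3 (2.198), Penk (2.06), Il12rb2 (2.04), Tbx6 (1.33) and Rab3d (1.33, log2). It was more downward for Rhd (-5.47), Slc4a1 (-5.08), Cldn13 (-4.68), Aldh1a1 (-4.25), Tlcd4 (-4.20), Kel (-4.17), Sphk1 (-3.94) and Rhag (-3.88). With values under log2 4 set to log2 4, Il12rb2 was 0.60, Il6 2.96 and Penk 1.97, and Tbx6 lay under log2 4 on all 12 arrays. For the other 12 genes all stimulated arrays of both genotypes lay under log2 4, so their difference is that of the resting cells. A fit on the 4 groups alone ended the calls of Slc4a1, Sphk1, Aldh1a1, Cldn13, Il6, Kel, Klrg1, Mcoln3, Penk and Rhag (adjusted p = 0.0796 to 0.108). Leaving out 1 array ended the call for Aldh1a1 without wild-type resting array 2 or 3, wild-type stimulated array 1, 2 or 3 or knockout stimulated array 1, 2 or 3 (adjusted p = 0.0539 to 0.0922), and for Cldn13 without wild-type resting array 3, wild-type stimulated array 1, 2 or 3, knockout resting array 1 or knockout stimulated array 1, 2 or 3 (adjusted p = 0.0555 to 0.102). It ended the call for Il6 without wild-type resting array 2 or 3 or wild-type stimulated array 3 (adjusted p = 0.0538 to 0.0707), and for Kel without wild-type resting array 2 or 3, wild-type stimulated array 1, 2 or 3 or knockout stimulated array 2 or 3 (adjusted p = 0.0520 to 0.0647). It also ended the call for Klrg1 without wild-type resting array 1 or 2, wild-type stimulated array 1, 2 or 3, knockout resting array 1 or knockout stimulated array 1, 2 or 3 (adjusted p = 0.0549 to 0.0918), and for Mcoln3 without wild-type resting array 2, wild-type stimulated array 2 or 3 or knockout stimulated array 2 or 3 (adjusted p = 0.0541 to 0.0616). The remaining calls lost were Penk without wild-type resting array 1, 2 or 3, wild-type stimulated array 2 or 3 or knockout stimulated array 2 or 3 (adjusted p = 0.0549 to 0.0936), and Rhag without wild-type resting array 2 or 3, wild-type stimulated array 1, 2 or 3, knockout resting array 1 or knockout stimulated array 1, 2 or 3 (adjusted p = 0.0609 to 0.106). Leaving out 1 array also moved these sizes by over 1.5 times as folds. Aldh1a1 was -5.17, Cldn13 -5.51, Rhag -4.89, Rhd -6.23 and Slc4a1 -6.09 without wild-type resting array 1. Aldh1a1 was -3.66, Cldn13 -3.66, Rhag -3.23 and Slc4a1 -4.48 without wild-type resting array 2. Aldh1a1 was -3.61, Cldn13 -3.98, Kel -3.17, Rhd -4.88 and Sphk1 -3.27 without knockout resting array 1. Klrg1 was 3.43 without knockout resting array 2 and Sphk1 -4.78 without array 3. Il6 was 2.81 without knockout stimulated array 1.

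In the comparisons of 3 with 3 arrays there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 5180 and 0 for wild-type and 5042 and 1 for knockout stimulated against resting cells, 1308 and 16 for knockout against wild-type cells at rest and 150 and 0 after stimulation. They were 4534 and 0 for XCT790 and 2283 and 1 for compound A against stimulated cells, 4940 and 0 and 4788 and 0 against resting cells, and 3617 and 1 for XCT790 against compound A.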

How the results depend on the processing

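The fits on the arrays numbered 2 and 3, with marker covariates and with stimulated knockout cells as the reference were chosen after the data were seen. Over all alternatives, the 271 gene results gave 4599 values: 4323 kept direction and side of the threshold, 254 lost the call, 18 gained it and 4 reversed. The 4 that reversed were Klf1 (-0.90) and Prtn3 (-1.16) in resting knockout against wild-type cells with the erythroid covariate, and Esrra with stimulated knockout cells as the reference (0.65 with XCT790 and 0.66 with compound A), where a reference that lacks the gene is the cause. Klf1 is 1 of the 5 markers in the covariate, which removes its own signal by construction; for Prtn3 the cause was not tested. For the counts that follow the cause was not tested, except where fewer genes or arrays enter. Signal under log2 4 limits folds to lower bounds. Quantile normalization was not run again, since over all probe sets the arrays already hold the same values.

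With no filter, knockout stimulated against resting cells gave 8197 genes, since more were tested. The floor of log2 6 gave 39 for the interaction and 0.872 for the compound A score. The mean of all probe sets gave 248 for stimulated knockout against wild-type cells. The array number as a block gave 123 for the interaction; of calls on lists in the comparisons whose numbers pair the samples, it gained cell cycle (knockout stimulation, adjusted p = 0.0462) and NF-kappaB feedback genes (resting knockout, 0.0400) and lost ATP synthase and CD8 markers (stimulated knockout, 0.0601 and 0.0910), and it changed no other call there beyond Cpt1a (stimulated knockout) and Il2ra (XCT790). Fits on the compared groups alone gave 176 for resting knockout against wild-type cells and 38 for the interaction. Array weights gave 2379 for resting and 1639 for stimulated knockout against wild-type cells, 1222 for the interaction and 4048 for compound A against stimulated cells. The limit of 2-fold, a stricter rule, left 2336 and 2153 for stimulation in wild-type and knockout cells, 252 and 49 for knockout against wild-type cells at rest and stimulated, 32 for the interaction, 1449 and 257 for XCT790 and compound A against stimulated and 2132 and 1830 against resting cells, and 764 between the inhibitors. The arrays numbered 2 and 3 gave 432 for stimulated knockout against wild-type cells and 574 for the interaction. The erythroid covariate gave 214 and the myeloid and neutrophil covariate 485 for resting knockout against wild-type cells. Score genes changed at least 2-fold gave 0.786 for XCT790 and 0.837 for compound A. Of 460 list tests, 175 passed with the preset and 5 with an estimated correlation. With fry, of 46 lists in each comparison, 38 and 42 passed for stimulation in wild-type and knockout cells, 10 and 0 for knockout against wild-type cells at rest and stimulated, and 0 for the interaction. For XCT790 and compound A fry passed 34 and 18 against stimulated and 38 and 37 against resting cells, and 29 between the inhibitors. Leaving out 1 array at a time gave 612 to 1487 genes for resting and 66 to 136 for stimulated knockout against wild-type cells, 22 to 141 for the interaction, and 0.854 to 0.869 for the compound A score.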

Other observations

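Amino acid transport and glutamine use genes rose in 11 of 12 with XCT790 against resting wild-type cells and fell in 1, the same adjusted over the list alone (adjusted p = 1.21e-04; 0.0180 with an estimated correlation). The large amino acid transporter subunits Slc7a5 and Slc3a2 were 7.78-fold and 7.10-fold higher, and the aminotransferase Gpt2 at least 10.98-fold. Against compound A, XCT790 cells had 6 of these 12 genes higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.0370; 0.149 with an estimated correlation). Cytoplasmic tRNA synthetases, which load amino acids for translation, rose in 15 of 18 with XCT790 and 17 with compound A against resting cells, the same adjusted over the list alone (adjusted p = 8.66e-06 and 1.22e-06; 0.437 and 0.490 with an estimated correlation). Cars was 34.9-fold and 10.5-fold higher. These comparisons cross the dap split, apart from that between the inhibitors, and the XCT790 arrays stood apart in quality controls.

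Targets of p53 were higher with XCT790 than with compound A in 8 of 16, the same adjusted over the list alone (adjusted p = 0.00296; 0.168 with an estimated correlation), among them Trp53inp1 (1.76-fold), the apoptosis gene Bbc3 (3.60-fold) and Mdm2, the ligase of p53 (1.49-fold). Pentose phosphate and nucleotide synthesis genes were lower in 11 of 20 and higher in 1, the same adjusted over the list alone (adjusted p = 0.0139; 0.462 with an estimated correlation), with Taldo1 2.04-fold and Dhodh 1.92-fold lower. Heat shock genes did not pass as a list between the inhibitors (adjusted p = 0.471; 4 higher and 3 lower of 14, the same adjusted over the list alone); Hspa1b was higher by 3.33 ± 0.67 (log2, SE) and Hspa1a by 3.30 ± 0.79 (adjusted p = 0.0835 in a fit on these 2 groups alone). As log2 differences, Hspa1a was 2.67 and 3.90 (from 3.30) without XCT790 arrays 1 and 2. Without compound A arrays 1 and 2 Hspa1a was 2.00 and 4.02 and Hspa1b 2.30 and 3.94 (from 3.33). Markers of NK cells fell in 11 of 13 with XCT790 against resting cells, the same adjusted over the list alone (adjusted p = 0.00348; 0.313 with an estimated correlation), including Nkg7 (62.4-fold) and Gzma (at least 20.4-fold).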
